A study of Mus musculus with 12 samples.

How the data were processed

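RNA from 12 mouse samples given as liver was profiled by RNA sequencing. The labels give each sample a genotype (wild type, or knockout of Hnf4a in the liver) and a diet (vivarium chow or high fat diet), which makes 4 groups of 3. The series design text calls the 3 samples of a group biological replicates. All 12 columns of the deposited table were mapped to samples by the sample titles, and 0 columns of values were left unmapped. Groups are written WT chow, WT HFD, KO chow and KO HFD, and each library is named by its label and its replicate number.

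The deposited values are FPKM, fragments scaled to gene length and library depth, computed by the authors for 35275 genes, with the gene length, coordinates and gene type in the same table per the file headers. Per the submitters' processing notes, CASAVA, TopHat, STAR, HTSeq 0.6.1 and DESeq2 (given as version 2) were used, with the builds GRCm38 and mm10. Which aligner made the deposited values, the annotation release, the strand setting and any filter are not given in the sources used here. Coordinates below are those of the deposited table, on GRCm38 (mm10). The table held 27 symbols that had become dates, which were restored from the gene identifiers, and 34490 identifiers matched the reference table of names. Reads from overlapping genes, antisense partners and near-identical family members may have been split or shared by the counting.

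Multiplying each FPKM by its gene length gave whole multiples of 1 step per library for 100% of values (tolerance 0.1 of a read), so the reads behind each value could be recovered. They summed to 15705196 to 20311766 reads on genes per library. A gene without a read in any library of a group was given a floor of 3 reads over the group, and its fold is written as a lower bound. The floor covers counting error only. Same-group libraries differed far beyond sampling noise (mean chi-square per gene from 39.2 to 1340), so none was treated as a repeat of another.

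The tests were fixed before the data were examined. Values were taken as log2(FPKM + 1), and a fold change on this scale understates the change of low genes. Genes with a mean FPKM of at least 0.5 over the 12 libraries were tested, 12251 in all, of which 11425 were annotated as protein-coding. All 12 libraries entered 1 fit with 4 group means in limma 3.58.1 (R 4.3.3, empirical Bayes with a trend), and 5 contrasts were read from it, with Benjamini-Hochberg adjustment and a threshold of 0.05. Hnf4a was also compared by exact two-sided permutation tests of FPKM. The 26 gene lists, with 468 genes of which 419 were tested, were tested with limma's camera at a preset correlation of 0.01, adjusted over 130 tests, then with camera's estimated correlation and with fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

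The genes named were set by rule. Hnf4a was given in every library. For each contrast, up to 10 genes with the highest and 10 with the lowest fold change were taken among those past the threshold with non-overlapping groups (this last condition not for the interaction) and a mean of at least 1 FPKM in the higher group, leaving out predicted and clone-named genes and pseudogenes. Where none passed, the 5 genes with the smallest p were given as values. For each list that camera called, or of which at least 25% of the tested members passed, up to 4 members past the threshold and 1 abundant member that did not pass could be named. Genes named outside this rule are said to be so.

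On simulated libraries of the comparison of KO HFD with WT HFD (11868 genes), 47% of genes changed 2-fold and 98.9% of those changed 4-fold were recovered, with 11 other genes called. When known changes were put into the real reads of that comparison (12247 genes), 2.02% of 2-fold and 35.1% of 4-fold changes were recovered with 12 libraries, and 36.4% and 72.2% with the 10 libraries left after the libraries labelled WT chow 2 and 3 were removed. In a simulated list test of the same comparison, a shifted list was called and 3 of 100 random lists fell under 0.05.

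Alternatives covered the pseudocount, the filter, scaling (TPM, median-of-ratios and quantile), the libraries in the fit, a replicate block, library weights, robust moderation, a fold threshold, and leaving out each library. Added after seeing the data were fits without the libraries labelled WT chow 2 and 3 (10 libraries), fits also without KO HFD 1 (9 libraries), and limma-voom on the recovered reads. In the fit with 10 libraries the estimated correlation gave many lists with strong and weak calls the same adjusted p. A call lost there therefore says little about a single list. Rescaling to TPM moved the median log2 change of all genes to 0.24 for KO against WT on chow, −0.13 on HFD, 0.11 for diet in WT, −0.23 for diet in KO and −0.37 for the interaction, against values between −0.10 and 0.08 as deposited. Quantile normalization moved it to −0.11 for diet in WT.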

Results

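Gene expression was measured by RNA sequencing in samples given as liver. They came from mice labelled wild type or Hnf4a liver knockout, fed vivarium chow or a high fat diet, with 3 libraries in each of the 4 groups. Hnf4a encodes a nuclear receptor that drives hepatocyte gene expression. The series title frames the question as the effect of the diet and of the loss of this factor on liver expression. Depth ran from 15705196 to 20311766 reads on genes per library.

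Hnf4a transcript (ENSMUSG00000017950, chromosome 2, 163506808 to 163572910, plus strand, protein-coding) was not lower by any test in the libraries labelled knockout. It stood at 158, 132 and 130 FPKM in KO chow 1 to 3 and at 108, 98.8 and 138 FPKM in KO HFD 1 to 3. The libraries labelled WT HFD held 133, 116 and 120 FPKM, and those labelled WT chow held 126, 75.8 and 0.0973 FPKM. On chow the mean was 140 FPKM in KO and 67.2 FPKM in WT, with KO the higher (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). On HFD the means were 115 and 123 FPKM (exact permutation p = 0.6, smallest possible 0.1), and over both diets 127 and 95.1 FPKM with 6 libraries each (exact permutation p = 0.182, smallest possible 0.00216). In the limma fit the log2 difference KO minus WT was 2.67 (SE 1.36, adjusted p = 0.273) on chow and −0.11 (SE 1.36, adjusted p = 1) on HFD. The fit pools the spread of all groups, and that of WT chow (0.0973 to 126 FPKM) largely sets this SE. The HFD libraries spanned only 98.8 to 138 FPKM. On HFD neither this fit nor a permutation of 3 against 3 could have called a modest fall. A whole-gene value can keep reads from exons that were not deleted and from cells other than hepatocytes, so they do not measure the deletion itself. Since Hnf4a does not follow the genotype labels, every direction between genotypes below is one between libraries labelled KO and libraries labelled WT.

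**Figure D1:**
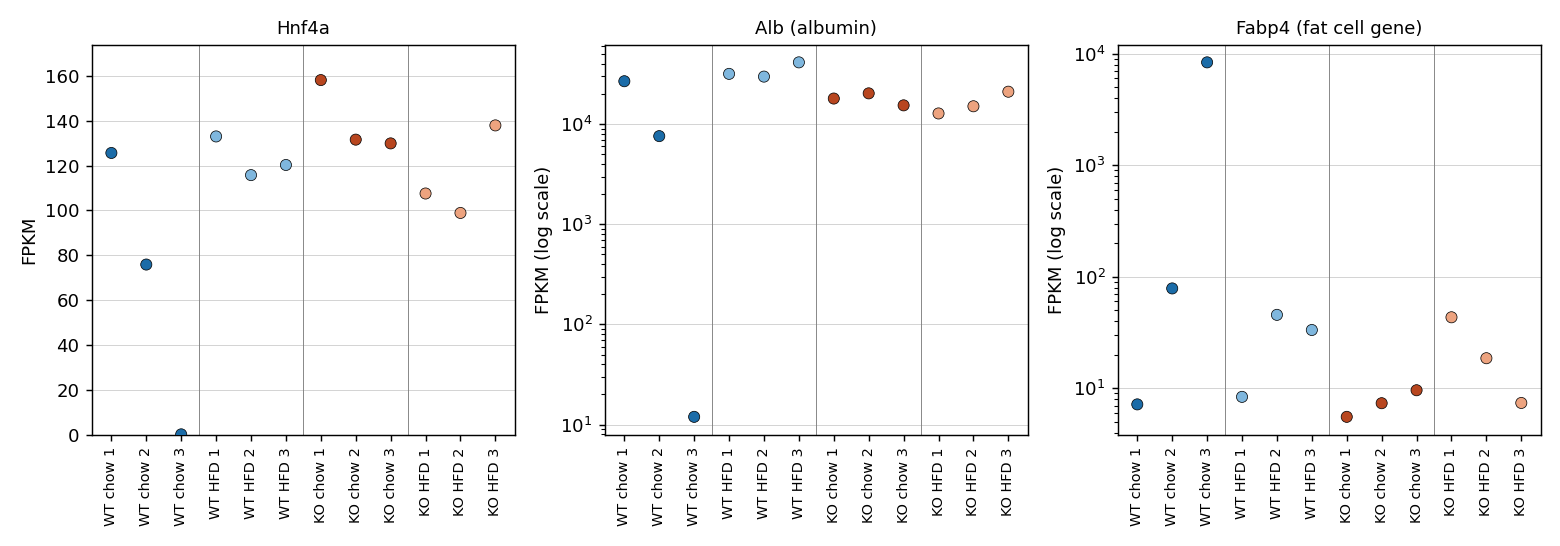
FPKM of Hnf4a (linear axis), Alb, which encodes albumin, and Fabp4, a fat cell gene (log axes), with 1 point per library and the 12 libraries grouped by label along the horizontal axis. The library labelled WT chow 3 held 0.0973 FPKM of Hnf4a, 11.9 of Alb and 8367 of Fabp4, and the library labelled WT chow 2 held 75.8, 7604 and 78.6.

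The libraries labelled WT chow did not resemble one another. WT chow 3 carried almost no hepatocyte transcript, with Alb at 11.9 FPKM against 7604 to 41503 FPKM in the other 11 libraries, and carried high levels of transcripts of brown fat, with Ucp1, the uncoupling protein of that tissue, at 2339 FPKM and Fabp4 at 8367 FPKM. Mitochondrial genes took 37.5% of its reads, against 3.39 to 6.26% elsewhere. WT chow 2 kept Alb at 7604 FPKM while Cyp2c29, a drug-metabolizing P450, stood at 0.545 FPKM against 663 in WT chow 1. Ucp1, Fabp4 and Cyp2c29 were singled out after their values were seen. Across genes, the median correlation with the other libraries was 0.576 for WT chow 3 and 0.806 for WT chow 2. Among the other 10 libraries every pairwise correlation lay between 0.931 and 0.988, with the lower end set by KO HFD 1. Genes are not independent replicates, and these correlations describe the libraries.

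Comparing KO with WT on chow asks what the knockout does under the control diet. Hepatocyte genes were at higher mean levels in the libraries labelled KO, but no gene passed the test. Cyp2d9, a male-biased P450, averaged 1022 ± 218 FPKM in KO chow and 335 ± 576 in WT chow (SD, n = 3), and Slco1b2, a hepatocyte uptake transporter, 352 ± 41.7 and 108 ± 184 FPKM. The 24 tested members of the list of HNF4A targets and hepatocyte identity were all higher by mean (median log2 difference 3.86), with 0 past the threshold over all genes and 16 when adjusted over the list alone. The 20 tested P450 and xenobiotic genes had a median of 3.91, with 0 past over all genes and 13 adjusted over the list alone. The 22 cholesterol synthesis genes had a median of 1.21, with 0 past and 10 adjusted over the list alone. The WT chow libraries differed widely in these genes, with a median of the HNF4A list, relative to WT HFD, of −0.10, −3.98 and −7.25 in WT chow 1 to 3.

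The smallest adjusted p on chow was 0.195 (limma), shared by the 5 genes with the smallest p once predicted and clone-named genes are left out. They were Ppat, a purine synthesis enzyme (log2 difference 1.25, SE 0.22), Acsl4, an acyl-CoA synthetase (1.05, SE 0.20), Whsc1l1 (1.06, SE 0.22), the clock gene Per2 (1.04, SE 0.22) and Efemp1 (1.61, SE 0.35). The count of genes past the threshold was 0 by limma on log2 FPKM and 0 by limma-voom on recovered reads, with 2584 genes at an unadjusted p under 0.05. Groups did not overlap for 2064 genes (16.8%), where chance gives 10%. Camera called 13 lists, and none held with an estimated correlation (HNF4A list adjusted p = 2.47e-07 with the preset correlation and 0.654 with the estimated one). Beyond those above, the called lists were bile acid, urea cycle, coagulation, lipoprotein, liver transcription factor, circadian and sex-biased genes, all upward, and fatty acid oxidation, lipid droplet and cell cycle genes, downward, with an adjusted p from 0.654 to 0.784 with an estimated correlation. In these 10 lists 0 members passed over all genes. Adjusted over the list alone, 6 bile acid, 5 coagulation and 5 sex-biased genes passed, with 6 circadian genes higher and 1 lower, and 0 in the other 6 lists. Leaving out WT chow 1, which leaves only the 2 libraries that stand apart in that group, raised the count from 0 to 2981 genes. Leaving out WT chow 2 and 3 instead, a choice made after seeing the data, called 1 gene, Dmbt1, at 17.2 FPKM in WT chow 1 and 0 to 0.0102 FPKM in KO chow (log2 difference −4.17), and 4 lists, none of which held with an estimated correlation (adjusted p from 0.765 to 0.839). In that fit the lone WT chow library is assumed to vary like the other groups, and the median of the HNF4A list was −0.07.

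Comparing KO with WT on HFD asks what the knockout does under the high fat diet. Transcripts of digestive enzymes of the exocrine pancreas rose in the libraries labelled KO HFD, and no gene passed as lower. Ctrb1 (chymotrypsinogen B, ENSMUSG00000031957, chromosome 8, 111686510 to 111691010) reached 24.5 ± 8.56 FPKM (SD, n = 3) with no read in WT HFD, at least 392-fold higher. Prss2 (a trypsinogen, ENSMUSG00000057163, chromosome 6, 41521787 to 41525079) reached 8.61 ± 2.10 FPKM, at least 127-fold higher, and Pnlip (pancreatic lipase, ENSMUSG00000046008, chromosome 19, 58670365 to 58681786) reached 5.63 ± 2.12 FPKM, at least 151-fold higher. The α-defensin Defa24 (ENSMUSG00000064213, chromosome 8, 21734494 to 21735471), a product of Paneth cells of the intestine, reached 4.79 ± 3.26 FPKM, at least 36.3-fold higher. Each of these was at 0 FPKM in the 3 WT HFD libraries. The summed FPKM of 8 heart muscle genes, chosen after values were seen, was 0.241 to 0.493 in KO HFD and 7.15 to 74.4 in the other 9 libraries.

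In all, 19 genes passed in limma, 19 higher and 0 lower, with log2 differences of 4.62 (SE 0.54, adjusted p = 0.00401) for Ctrb1, 3.24 (SE 0.17, adjusted p = 1.47e-05) for Prss2, 2.68 (SE 0.21, adjusted p = 1.98e-04) for Pnlip and 2.40 (SE 0.30, adjusted p = 0.00631) for Defa24. The other genes named by the rule were Try4 (3.16), Try5 (2.87), the elastase Cela3b (2.62), the colipase Clps (2.44), the zymogen granule gene Sycn (1.97) and the protease Ctrl (1.96). Prss2, Try4 and Try5, and the defensins, are near-identical families whose reads could be split, so their single values are uncertain. The list of adipocyte, pancreas and blood genes, markers of other tissues, was called by camera (adjusted p = 2.62e-06) and held with an estimated correlation (adjusted p = 0.0387). In the fit without WT chow 2 and 3 it was called by camera at the preset correlation and by fry, but not with an estimated correlation. Of its 12 tested members 4 rose over all genes and 4 when adjusted over the list alone, namely Pnlip, Cpa1, Cel and Cela2a. Its mean was 0.28 and its median −0.29, which differ in sign. Hba-a1, a globin, stood at −0.71 and did not pass.

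**Figure D2:**
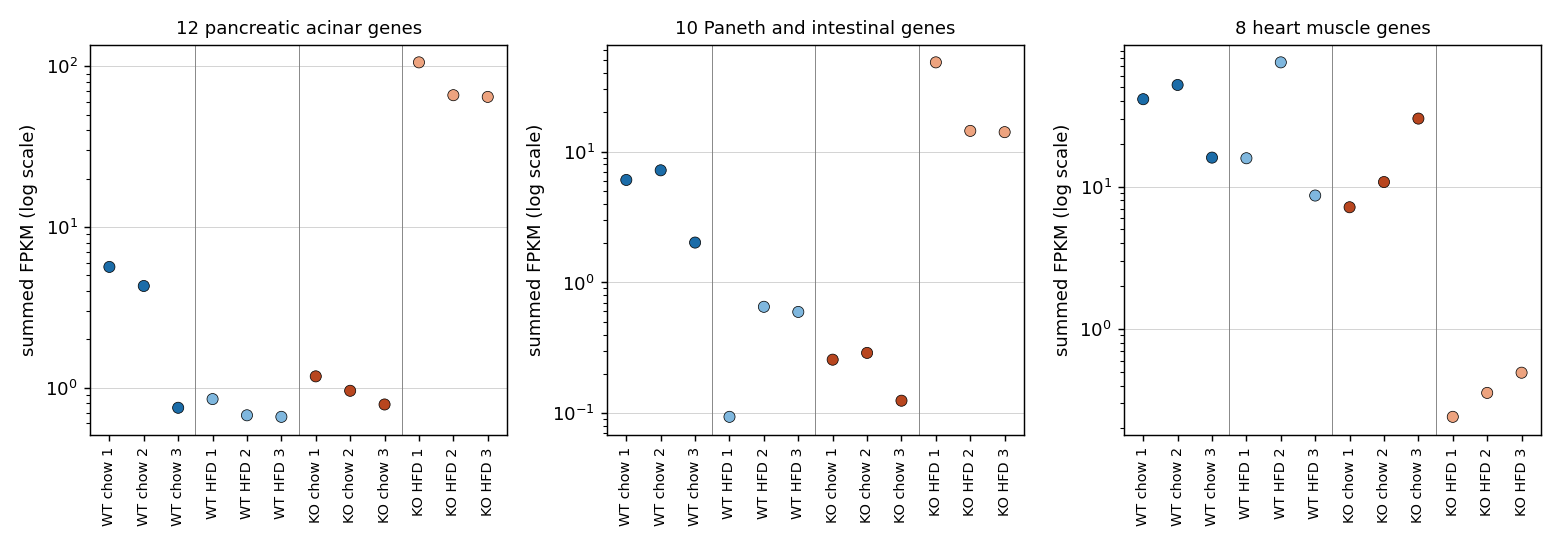
Summed FPKM (log axes) of 12 pancreatic acinar, 10 Paneth and intestinal and 8 heart muscle genes, with 1 point per library and the 12 libraries grouped by label along the horizontal axis. The acinar sum was 106, 66.2 and 64.6 FPKM in KO HFD 1 to 3 and at most 5.65 FPKM in the other 9 libraries. The gut sum was 48.3, 14.4 and 14.1 FPKM in KO HFD 1 to 3, 6.09 and 7.21 in WT chow 1 and 2 and at most 2.02 in the other 7. The heart sum was at most 0.493 FPKM in KO HFD and at least 7.15 FPKM in the others.

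On HFD the HNF4A list had a median log2 difference of −0.27 with 0 of 24 members past (adjusted p = 0.447, camera). In the fit without WT chow 2 and 3, chosen after seeing the data, camera called this list downward (adjusted p = 0.0251), with 0 members past, and the call was lost with an estimated correlation (adjusted p = 0.765). Rescaling gave −0.40 with TPM (adjusted p = 0.0638), −0.24 with median-of-ratios (0.0384) and −0.38 with quantile normalization (0.00127). The call rested on KO HFD 1, since the median relative to WT HFD was −0.69, 0.02 and −0.17 in KO HFD 1 to 3, and without KO HFD 1 as well the median difference was −0.06 (adjusted p = 0.886). Camera called 4 lists besides the one above, none of which held with an estimated correlation. These were acute phase and inflammation (median 0.76, 0 of 18 past, adjusted p = 1.27e-04 and 0.654 with an estimated correlation), cell cycle (0.31, 0 of 24 past, 0.00135 and 0.693), circadian clock (−0.37, 0 of 18 past, 0.00125 and 0.654) and sinusoidal endothelial cell (−0.24, 0 of 12 past, 0.0297 and 0.654). Each of these 4 lists had 0 members past when adjusted over the list alone. At an unadjusted p under 0.05 there were 156 genes, voom called 15, and groups did not overlap for 2428 genes (19.8%, chance 10%). A filter of mean FPKM of at least 2 gave 3 genes, but it leaves genes such as Pnlip, with reads in KO HFD only, untested. Array weights gave 33.

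The diet comparison in WT asks what the high fat diet does where Hnf4a is labelled intact. As in the chow comparison, hepatocyte genes were at higher mean levels in the libraries not belonging to WT chow, and no gene passed. Dsg1c, a desmosomal cadherin, averaged 18.6 ± 4.68 FPKM in WT HFD and 1.89 ± 2.28 in WT chow (SD, n = 3), and Per2 averaged 6.39 ± 0.669 and 1.79 ± 0.904 FPKM. The 24 HNF4A list members were all higher by mean (median 3.73, 0 past over all genes, 12 adjusted over the list alone). This difference rested on WT chow 2 and 3, and without these libraries the median of the list was 0.10.

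Leaving out predicted and clone-named genes, the 5 genes with the smallest p, all at an adjusted p of 0.307 (limma), were Per2 (log2 difference 1.45, SE 0.22), Dsg1c (3.07, SE 0.56), Gatm, a creatine synthesis enzyme (1.66, SE 0.31), Map2k6, a kinase of the p38 pathway (1.87, SE 0.37), and the Polycomb gene Pcgf2 (−1.49, SE 0.30). The count was 0 by limma on log2 FPKM and 0 by voom, with 1807 genes at an unadjusted p under 0.05 and 1369 genes (11.2%, chance 10%) whose groups did not overlap. Camera called 12 lists and none held with an estimated correlation (HNF4A list adjusted p = 3.28e-10 with the preset correlation and 0.654 with the estimated one, the latter shared by all 12). The others were liver transcription factor, lipoprotein, bile acid, gluconeogenesis, urea cycle, coagulation, P450, circadian, sex-biased and sinusoidal endothelial lists, upward, and fatty acid oxidation, downward. In these 11 lists 0 members passed over all genes, and adjusted over the list alone 6 coagulation, 7 circadian, 5 sex-biased, 1 bile acid and 1 endothelial gene passed. Leaving out WT chow 1 raised the count from 0 to 2435 genes. Without WT chow 2 and 3 there was 1 gene, Dmbt1 (−4.12), which is the gene high in WT chow 1. In that fit the cholesterol list had a median of −1.34. With 12 libraries its median was −0.19 and camera did not call it (adjusted p = 0.411). Of its members 21 of 22 lay lower in every WT HFD library than in WT chow 1, a single library.

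The diet comparison in KO asks what the high fat diet does where the label says that Hnf4a is lost. The same pancreatic and Paneth cell genes rose in KO HFD. Genes of cholesterol synthesis were at lower mean levels in KO HFD, and 22 of 22 tested members lay lower by mean. Idi1, an isoprenoid enzyme of the pathway, averaged 17.5 ± 3.44 FPKM in KO chow and 3.41 ± 3.82 in KO HFD (SD, n = 3). Sqle, which encodes squalene epoxidase, averaged 13.4 ± 2.47 and 3.49 ± 3.94 FPKM.

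In limma 19 genes passed, 19 higher and 0 lower, among them Ctrb1 (log2 difference 4.62, SE 0.54, adjusted p = 0.00432, at least 377-fold higher) and Prss2 (3.24, SE 0.17, adjusted p = 1.47e-05, at least 122-fold higher). The 19 genes are the same 19 as in the comparison with WT HFD. Independent lists of this size would share 0.0295 genes, but these lists are not independent, since both contrasts use the same KO HFD libraries. Ctrb1, Prss2 and Pnlip averaged 0 FPKM in KO chow and in WT HFD, so both contrasts set the same KO HFD values against 0. Unchanged groups simulated with these shared libraries shared 0.01 on average over 100 draws, at most 1. That simulation held no changed gene, so it cannot measure the sharing among the 19. The overlap is therefore not a second line of evidence. At an unadjusted p under 0.05 there were 924 genes, voom called 12, and 3865 genes (31.5%, chance 10%) did not overlap. The count of 19 rose far with array weights and fell with a filter of mean FPKM of at least 2, as given in the part on processing. The cholesterol list was called (median −1.23, camera adjusted p = 7.78e-08) but 0 of 22 members passed, 0 adjusted over the list alone, and the call was lost with an estimated correlation (adjusted p = 0.654). The list of adipocyte, pancreas and blood genes held (adjusted p = 8.89e-08, and 0.0354 with an estimated correlation). Without WT chow 2 and 3 it was called by camera at the preset correlation and by fry, but not with an estimated correlation. Of its 12 members 4 rose over all genes and 4 adjusted over the list alone. Cell cycle (median 0.39), acute phase (0.73), macrophage and Kupffer cell (0.67) and lipid droplet (0.24) lists were called upward, with 0 members past and an adjusted p of 0.654 with an estimated correlation in each.

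**Figure D3:**
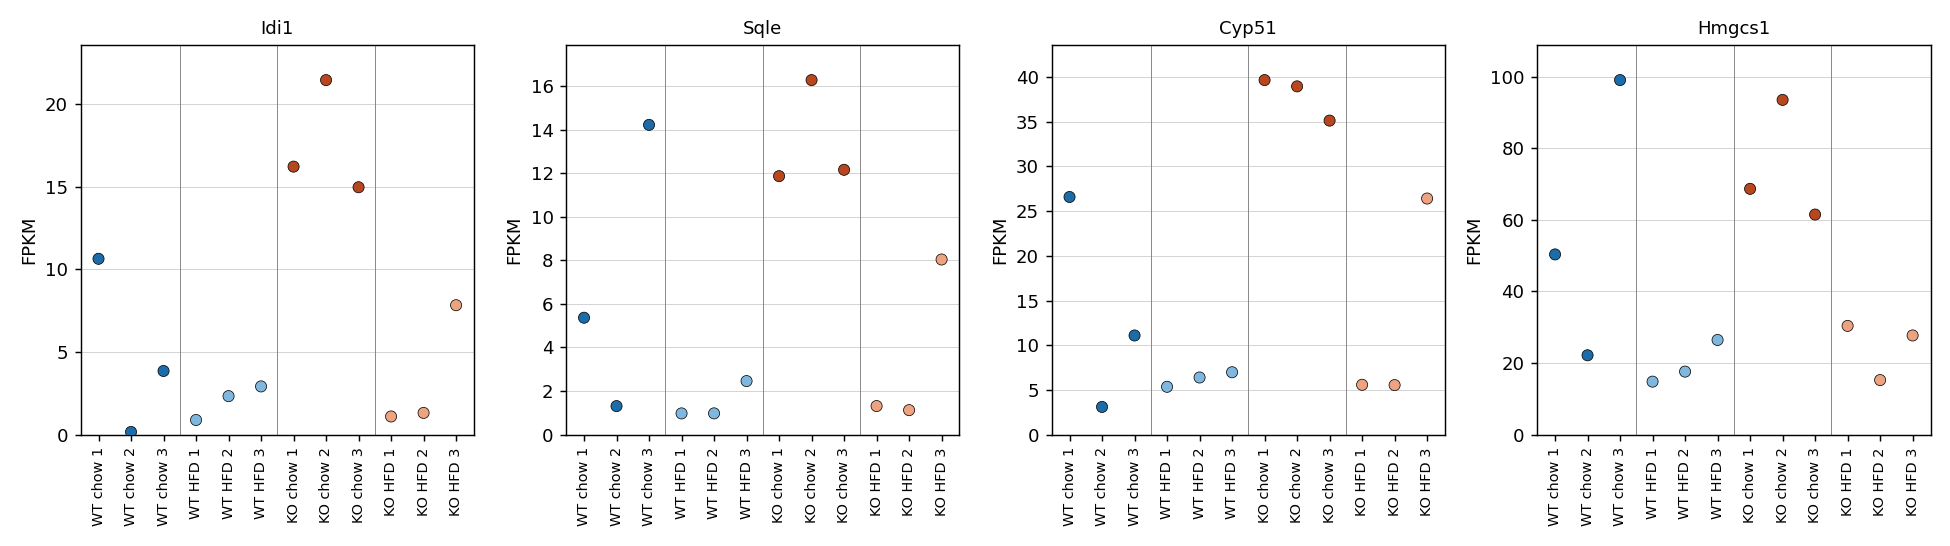
FPKM (linear axes) of Idi1, Sqle, Cyp51 and Hmgcs1, genes of cholesterol synthesis, with 1 point per library. In KO chow, Hmgcs1 lay between 61.4 and 93.5 FPKM, and in KO HFD between 15.2 and 30.4. KO HFD 3 held Cyp51 at 26.4 FPKM against 5.57 and 5.53 in KO HFD 1 and 2.

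Without WT chow 2 and 3, a choice made after seeing the data, the diet comparison in KO gave 951 genes, 186 higher and 765 lower, by limma, including the 19. In that fit 10 of 22 cholesterol genes fell over all genes and 17 adjusted over the list alone (camera adjusted p = 4.84e-08, and 0.765 with an estimated correlation), among them Hmgcs1 (−1.61, SE 0.29, adjusted p = 0.0334), Cyp51 (−1.88, adjusted p = 0.0450), Sqle (−2.02, adjusted p = 0.0445) and Idi1 (−2.39, adjusted p = 0.0363). Of 20 lipogenesis genes, 4 fell and 1 rose, with 7 and 1 adjusted over the list alone (camera adjusted p = 0.135, and 0.765 with an estimated correlation). Those that fell included the desaturase Scd1 (−1.59, adjusted p = 0.0371) and the fatty acid synthase Fasn (−1.07, adjusted p = 0.0441). The P450 genes Cyp2c55 (−2.69, adjusted p = 0.00155) and Cyp2b10 (−2.18, adjusted p = 0.0340) also fell, as did Krt14 (−2.33) and Myl2 (−2.09), genes of stratified epithelium and of heart muscle. The count of 951 rested on the libraries kept. It was 18 also without KO chow 1 (2 lower), 17 without KO chow 2 (1 lower), 1535 without KO chow 3 (1139 lower), 39 without KO HFD 1 (15 lower), 396 without KO HFD 2 (337 lower) and 88 without KO HFD 3 (45 lower). In the same order 0, 0, 8, 1, 3 and 12 cholesterol genes and 0, 0, 5, 0, 1 and 0 lipogenesis genes fell, so the excess of lower genes was lost without KO chow 1, KO chow 2 or KO HFD 1 and nearly so without KO HFD 3, and no lipogenesis gene fell without any 1 of these 4. The median of the cholesterol list was −1.23 with 10 libraries (median SE 0.34) and −1.30, −1.14, −1.38, −1.07, −1.17 and −1.66 in the same order (median SE 0.26 to 0.41), so calls ended while the fold stayed of similar size. A fit of the 6 compared libraries alone gave 20, 19 of them among the 951. With TPM the count of 951 became 2224 (93.3% lower), with median-of-ratios scaling 978 of which 55.6% were lower instead of 80.4%, and with quantile normalization 370 (66.2% lower). In the order TPM, median-of-ratios and quantile, 17, 6 and 3 cholesterol genes and 8, 3 and 4 lipogenesis genes fell, and the median of the cholesterol list was −1.48, −1.12 and −1.37.

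The interaction asks whether the diet effect differs between the genotypes as labelled. Again the pancreatic genes stood out in limma, with Ctrb1 (5.44, SE 0.77, adjusted p = 0.0262), Prss2 (3.24, SE 0.24, adjusted p = 5.09e-04) and Pnlip (2.68, SE 0.29, adjusted p = 0.00587). They were higher in KO HFD than in KO chow, with no rise from chow to HFD in WT. A handling batch that coincides with KO HFD cannot be told apart from a diet effect here. In WT, Prss2 and Pnlip had no read on either diet, and Ctrb1 averaged 1.49 FPKM on chow, all from WT chow 1, and 0 on HFD, which adds to its interaction. In limma 15 genes passed, 15 positive and 0 negative, all among the 19 above. Hepatocyte lists had negative medians (HNF4A list −4.13, 0 of 24 past, 0 adjusted over the list alone); without WT chow 2 and 3 the median of the HNF4A list was −0.22. Camera called 13 lists, and none held with an estimated correlation (smallest adjusted p = 0.317). Of the 12 adipocyte, pancreas and blood genes 3 passed over all genes and 4 adjusted over the list alone, both positive. The circadian list had 0 past over all genes, and 1 positive and 8 negative adjusted over the list alone. The other called lists had 0 by either adjustment.

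The count of 15 depended on single libraries. It was 2265 without WT chow 1, 8 without WT chow 2, 5 without any 1 of the WT HFD or KO chow libraries, and 9 without KO HFD 2 or without KO HFD 3. It was 0 by voom with 12 libraries, while 2038 genes had an unadjusted p under 0.05.

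Across the 12251 genes, the KO minus WT differences on the 2 diets correlated at Pearson r = −0.318 (Spearman −0.469), and the diet effects in the 2 genotypes at r = −0.245 (Spearman −0.339). Genes are not independent replicates, and each pair of contrasts shares no library. The first was −0.0967 without WT chow 2, −0.519 without WT chow 3 and −0.0426 without KO HFD 1, and −0.204 (Spearman −0.308) without both WT chow 2 and 3. The second was 0.0184, −0.467, −0.0357 and 0.169 (Spearman 0.0896) in the same order.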

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

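The interaction tests were planned, while the counts of other splits of the libraries and every test of an explanation in this part were chosen after the result was seen.

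In the limma interaction test, 15 genes passed as differing by diet between the genotypes as labelled, each with a positive value. The log2 interaction was 5.44 for Ctrb1, 3.27 for Try5, 3.24 for Prss2, 3.16 for Try4, 3.01 for Cela3b, 2.68 for Pnlip, 2.48 for Clps, 2.23 for Ctrl, 2.05 for Sycn, 1.93 for Defa22, 1.91 for Cpa1 and 1.76 for Cel. Of 100 drawn splits of the 12 libraries, 2 gave as many genes, the real split included, a share under 0.05. The highest of the other splits gave 15 as well, and it left the KO groups intact and only exchanged WT libraries. For the interaction camera, which sets a list against the other genes, called 13 lists. Their median log2 interactions were −4.13 (HNF4A targets and hepatocyte identity), −4.56 (P450 and xenobiotic genes), −3.09 (coagulation), −3.07 (urea cycle), −2.94 (lipoprotein), −2.15 (sex-biased genes), −2.06 (bile acid), −1.46 (liver transcription factors), −1.34 (circadian clock), −1.05 (cholesterol synthesis), 0.69 (cell cycle), 1.55 (lipid droplets) and 1.31 (adipocyte, pancreas and blood genes). None of the 13 held with an estimated correlation (adjusted p from 0.317 to 0.784). Without WT chow 2 and 3 the same medians were, in this order, −0.22, −0.09, 0.01, 0.21, 0.35, −0.39, −0.12, −0.46, −0.53, −0.13, 0.25, 0.11 and −0.34.

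For the comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. KO against WT on HFD gave 19 genes and the highest other split 0, so that 1 of 10 splits reached the real count, and the diet comparison in KO gave the same figures. KO against WT on chow and the diet comparison in WT gave 0 genes in the real split and 0 in every other, so that 10 of 10 splits reached it.

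The libraries labelled WT chow 2 and 3 stood apart from the rest, and KO HFD 1 deviated in the direction of WT chow 2 (correlation across genes 0.665, against −0.532 to 0.165 for the other KO libraries, partly negative by construction in KO HFD 2 and 3). Lower depth is argued against, since 7 other libraries held fewer reads than WT chow 2 and had a median correlation of at least 0.948, and 2 held fewer than WT chow 3 and had at least 0.971, against 0.806 and 0.576 for WT chow 2 and 3. Brown adipose tissue in place of liver is a candidate explanation for WT chow 3, where 12 of 12 brown adipose genes had their highest FPKM and 12 hepatocyte transcripts stood at a median of 0.0351% of the other libraries; 5 of those 12 genes were expressed at 1 FPKM or more in the other libraries and 5 belonged to lists fixed in advance. RNA of WT chow 2 mixed into KO HFD 1 would lower the 4 Y-linked genes, which stood at 4.12 to 8.32% of the usual level in WT chow 2. They were not lower in KO HFD 1 (median log2 ratio 0.39, SD 0.33, against −0.48 for the HNF4A list). The test cannot exclude a mixture, since this SD is a spread among 4 genes and not between libraries. The Y-linked sum was 32.4 FPKM in KO HFD 1, 32.1 and 23.7 in KO HFD 2 and 3, and up to 41.5 in KO chow 2. What WT chow 2 holds stays open, with 6 of 12 hepatocyte transcripts below and 3 above all other 10 libraries, and no biological explanation was tested.

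Hnf4a was not lower by any test in the libraries labelled knockout. On HFD, however, the permutation could not have called a fall of any size, and the limma fit could not have called a modest one. A full loss of the protein could be hidden by reads from exons that were not deleted. The HNF4A list had a median log2 change of −0.27 (SD 0.42 among its 24 members) in KO HFD against WT HFD. This lies above the −1 set for a full loss after values were seen. It argues against a full loss only under that limit, which was not calibrated here. A partial loss stays open. The downward call of the HNF4A list with 10 libraries does not settle it, as the call was lost without KO HFD 1 (median −0.06). Rescaling left the median between −0.24 and −0.40. The call was also lost with an estimated correlation, but in that fit this happened to lists with far stronger calls too, such as cholesterol synthesis for diet in WT. Genotype labels that do not follow the deletion cannot be told apart from a deletion that leaves the transcript in place, because 4 of the 6 libraries labelled knockout had Hnf4a above the lowest WT HFD library and no other measure of the genotype was analysed here.

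Pancreatic and intestinal transcripts were highest in the 3 KO HFD libraries (gut sum 14.1 to 48.3 FPKM). Of markers chosen after values were seen, 12 of 12 acinar and 8 of 10 gut genes were higher in each KO HFD library than in each of the other 9. RNA of pancreas and gut carried into these samples cannot be told apart from expression in liver, since either would raise these transcripts. Of 6 pancreatic genes in a list fixed in advance 4 were higher in each KO HFD library than in each of the other 9. Prss1 had no read in any library and Cela1 stood at 24.9 to 90.1 FPKM throughout, so neither was informative. No gut gene was in such a list. Lower levels were also seen without the knockout label or the diet, with a gut sum of 6.09 FPKM in WT chow 1 and 7.21 in WT chow 2, and Ctrb1 at 4.47 FPKM in WT chow 1 against up to 34.3 in KO HFD. A handling batch that coincides with the group cannot be told apart from the group itself, since 7 of 8 heart genes were also lower in each KO HFD library than in each of the other 9 and the labels give no batch. Expression by liver cells of mice with both the knockout and the diet was not tested.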

How the results depend on the processing

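Alternatives were fixed in advance except the fits with 10 and 9 libraries and those with voom, which were chosen after seeing the data. Hnf4a kept its side of the threshold in every contrast and setting run. The count of genes for KO against WT on HFD, 19, stayed between 15 and 28 except where given here. The edgeR alternative was planned only for a file of counts and was not run, and voom on the recovered reads was added instead. Depth was similar between libraries (15705196 to 20311766 reads). Where no construction of the setting explains a value below, the cause was not tested.

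Genes past the threshold were 0 for KO against WT on chow, 19 for KO against WT on HFD, 0 for diet in WT, 19 for diet in KO and 15 for the interaction. Without a filter on low values KO on chow became 4, diet in KO 31 and the interaction 25. A mean FPKM of at least 2, which tests fewer genes, gave 3 for KO on HFD, 3 for diet in KO and 1 for the interaction. Array weights gave 33, 2420 and 7 in the same order, and a pseudocount of 0.1 gave 6 for the interaction. With 10 libraries KO on chow was 1, diet in WT 1 and diet in KO 951, and with 9 libraries these were 3, 3 and 39 and the interaction 24. Voom with 12 libraries gave 12 for diet in KO and 0 for the interaction. With 10 libraries voom gave 1 for KO on chow, 1 for diet in WT, 1227 for diet in KO and 2 for the interaction. Leaving out single libraries gave 0 to 2981 for KO on chow, 16 to 20 for KO on HFD, 0 to 2435 for diet in WT, 14 to 20 for diet in KO and 5 to 2265 for the interaction, where 2981, 2435 and 2265 arose without WT chow 1.

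Lists called, 13, 5, 12, 6 and 13 in the order of contrasts above, became 0, 1, 0, 1 and 0 with an estimated correlation and 0, 1, 0, 1 and 1 by fry. KO on chow, diet in WT and the interaction had 4, 6 and 6 with 10 libraries and 3, 7 and 7 with 9. Leaving out single libraries gave 9 to 14, 4 to 7, 11 to 13, 6 to 7 and 8 to 17, the 8 without WT chow 3. The correlation of knockout effects, −0.318, was −0.204 with 10 libraries, −0.177 with 9, −0.683 over genes past a threshold and −0.519 to −0.0426 without single libraries. The correlation of diet effects, −0.245, was 0.169 with 10 libraries, 0.179 with 9, −0.556 over genes past a threshold and −0.467 to 0.0184 without single libraries, reversed without WT chow 2.

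The replicate numbers do not pair the samples. Of 18 same-number pairs 2 had correlated deviations over 0.1 (range −0.504 to 0.131), and 2 of 12 libraries correlated best with their own number. With the number as a block, the counts of genes were 0, 18, 0, 17 and 4 and those of lists 13, 7, 12, 6 and 15. For genes named singly, planned settings left 2220 values on their side of the threshold, moved 51 past it and 106 out. Added settings gave 236, 26 and 4 in the same order. A change of direction was counted only for values past the threshold in the main fit or in the setting, and 0 were found.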

Other observations

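The genes in this part were picked out after their values were seen, apart from the cholesterol list, which was fixed in advance, and values per library are given here without tests.

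A pair of P450 genes followed the diet label in the libraries other than WT chow 2 and 3, except in KO HFD 3. Cyp2b10 stood at 7.72 FPKM in WT chow 1 and 6.84 to 7.56 in KO chow, and at 0.0864 to 0.245 FPKM in the WT HFD libraries and KO HFD 1 and 2, with 3.49 FPKM in KO HFD 3. Cyp2c29 stood at 663 FPKM in WT chow 1, 539 to 701 in KO chow, 60.3 to 176 in the same 5 HFD libraries and 534 in KO HFD 3. The cholesterol list showed the same library nearest to chow, with a median log2 distance from KO chow of −0.59 in KO HFD 3 against −1.60 and −1.42 in KO HFD 1 and 2. Of the acute phase transcripts, Saa1 spread widely within both HFD groups and Lcn2 within WT HFD. Saa1 stood at 374, 576 and 2430 FPKM in KO HFD 1 to 3 and at 47.5, 186 and 675 FPKM in WT HFD 1 to 3, so that the groups overlapped. Lcn2 stood at 83.6 to 91.2 FPKM in KO HFD and at 2.44, 13.5 and 99.2 FPKM in WT HFD 1 to 3.

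WT chow 2 held high levels of several transcripts that were also high in KO HFD 1. Hamp2 stood at 3130 and 1622 FPKM in these 2 libraries and at most at 59.5 FPKM in the other 10, Acot1 at 1006 and 319 FPKM against at most 15.2, Defb1 at 202 and 61.4 against at most 2.03, and Anxa13 at 85.8 and 76.7 against at most 2.67. Gsn was higher in KO HFD 1 (1445 FPKM) than in WT chow 2 (566 FPKM). Mki67, a proliferation marker, stood at 2.86 and 1.54 FPKM in these libraries and at most at 0.435 FPKM elsewhere. The Y-linked transcripts of WT chow 2 summed to 1.65 FPKM, against 23.7 to 41.5 FPKM in the other 11 libraries, with Xist at 0.0717 FPKM.

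Transcripts of further tissues differed between single libraries. The sum of 6 skeletal muscle genes was 116 FPKM in WT HFD 2 and 53.2 in WT chow 3, and 1.11 to 3.03 FPKM in the other 10. Krt14 and Krt5, keratins of stratified epithelium, summed to 0 to 0.140 FPKM in the KO HFD libraries and 0.101 in WT HFD 2, and to 3.98 to 10.1 FPKM in the other 8.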
